A study of Mus musculus with 194 samples.

How the data were processed

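The series holds 194 single-cell libraries made with CEL-Seq2 per the labels' protocols, each a plate file with 96 named wells and as many empty ones. The deposited values are transcript counts per gene and well that the authors had corrected for saturation of the unique molecular identifiers (UMIs), a unit listed as other. Every one of the 30397631 values above 0 became whole (within 0.01) when the correction for 4096 possible UMIs of 6 bases was undone. Per the labels, reads were converted with bcl2fastq 2.17.1.14 and mapped with BWA 0.6.2-r126; the genome build is not given in the sources used here. Gene names follow the GENCODE basic M9 gene groups deposited with the series. Coordinates printed in the text come from GENCODE M21 and were used only to say where 3 genes lie, with no deposited coordinate beside them. No 2 files held identical values.

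Groups came from the sample labels, and mouse, gate and cell origin came from the deposited well names. Of 18624 named wells, 11 on 1 lung plate carried marrow names and were left out. Neonatal titles carry P8, which is not explained, while the age label gives postnatal day 4, and the age label was followed. For 1 parabiont library of the CD45.2 host of pair 1 the title gives experiment 2 and the description experiment 1; title and well names were followed. A well was kept as a cell with at least 1000 transcripts, spike-ins (85 names) left out: 15533 cells passed and 3080 did not. Empty wells held 0.0587% to 14.7% of a library's transcripts (median 2.91%), and the highest median empty well held 569.6. Library totals ran from 57260 to 988135 transcripts (median 492212). Cells per group ranged from 293 in the lung progenitor gate to 2590 in the chimeras among in vivo groups, and median transcripts per cell from 3662 (lung progenitor) to 7712 (neonatal). No doublet search was run, since each well was sorted to hold 1 cell.

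The replicate was the animal, or for chimeras the unit of the library titles, which do not map one to one onto the animals named in the wells. Cells of 1 animal or unit, and of 1 gate or origin where these were compared, were summed. Marrow was represented by the Lin-Il18r1+Icos+ wells. Parabionts gave 8 animals with both origins and chimeras 4 of 5 units with at least 20 cells of each origin. Cultures gave 8 arms (tissue, stroma and IL-18), each with 1 sum, so a factor was tested as 4 arms against 4 with the other factors as covariates. The parabionts, chimeras and marrow gates were fitted with the animal or unit as a block. Groups with no separate animals gave sums with exact 95% Poisson intervals. Other culture groups were not compared. Comparisons of whole parabionts or chimeras with resting lung, planned only if wells had no origin, were not run.

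The design had foreseen a count model, but the unit check could not reach the columns of these files, so the values were listed as other and tested on a log scale. Sums were scaled by trimmed means of log ratios and genes were kept with about 10 transcripts at the median library in enough samples and at least 15 in all. Values became log2 CPM after adding 2 (scaled to library size), so folds of low genes are understated, except in marrow against lung. The limma test used moderated variances with a trend, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Marrow, resting lung and days 4, 7 and 15 shared 1 fit of 12324 genes. For marrow against lung alone, precision weights (voom) were used, a choice made after both counts were seen, 2217 with weights and 3600 without. That fit added only 0.5 to the transcripts, so its folds of low genes are larger, and for genes near 0 in either group they rest on few transcripts. The reason was a test with simulated changes in 200 genes, in which 50 unchanged genes were called without weights and 26 with them. In those simulations 85.6% to 100% of 2-fold changes were found over the 13 comparisons, and 100% of 4-fold changes. The changed genes all had a mean of at least 50 CPM. Every gene was given the median spread of genes with similar expression. These shares do not hold for low genes or genes that vary more between animals.

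There were 19 gene lists, written before the data were examined, as were the groups, the comparisons, the marker lists, the rule for naming genes and the first set of alternatives. They cover ILC2 identity, ILC2 effector cytokines, ILC progenitors, ILC3, ILC1 and NK, T cells, B cells, myeloid cells, basophils and mast cells, erythroid cells, lung epithelium and endothelium, stroma, proliferation, MHC class II, migration and residency, immediate-early and stress genes, interferon response, glycolysis, and inhibitory and activating receptors. Each list with at least 3 measured genes was tested with limma camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Rose and fell are used of genes with an adjusted p under 0.05; counts adjusted over the list alone correct over that list's genes. Single-sample lists give the median log2 ratio of genes with at least 5 CPM and its percentile among 10000 random lists of the same size.

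Genes were named by a fixed rule. Among genes with an adjusted p under 0.05, at least 50 CPM in the higher group mean and no overlap between animals (the same sign in every animal for blocked fits), the 10 largest changes in each direction qualified. Up to 3 passing members of each list with the smallest adjusted p qualified too, as did 13 panel genes: Gata3, Il1rl1, Il18r1, Icos, Klrg1, Arg1, Il5, Il13, Areg, Tcf7, Zbtb16, Cd74 and Mki67. The text names part of the genes that qualified, and some genes are not reported here. For single samples the 10 highest and 10 lowest ratios qualified, among genes with at least 50 CPM and a ratio over 2 against every animal of the other group; folds against 0 use a floor of 3 counts over the group. Single-sample folds are ratios of CPM with no scaling for composition.

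Cells were clustered on 2000 variable genes (proliferation, ribosomal, mitochondrial and spike-in genes left out), 30 principal components, 15 neighbours and Leiden resolution 1, in vivo and cultured cells apart, with no batch integration. A cluster was called X-like when at least 3 markers of 1 class were among its 50 leading genes and led those of other classes; others stayed unnamed. Shares of donor and host cells were compared by an exact two-sided sign-flip permutation test.

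Alternatives recomputed were median-of-ratios scaling, no low filter, cells with at least 500 or 2000 transcripts, leaving out cells of other named types, ILC2-like cells alone, cells thinned to 1000 transcripts, added values of 0.5 and 5, voom weights, fits of only 2 groups, blocks by mouse number, single experiments, clustering at resolutions 0.5 and 1.5, and leaving out each animal. Alternatives based on a count model were not run because of the unit. Leaving out 1 mouse of the marrow gate comparisons left no residual degrees of freedom, so these gave no values. Versions: Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, leidenalg 0.10.2, scikit-learn 1.9.0, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.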

Results

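Single-cell CEL-Seq2 libraries profiled innate lymphoid cells (ILCs) of the mouse, above all group 2 ILCs (ILC2), which make type 2 cytokines, and their progenitors. The 194 plate libraries fell into 29 groups: bone marrow, neonatal and adult lung, lung and blood after infection with a helminth (marked NB in the labels), parabiotic pairs, shield chimeras and cultures. The parabionts and shield chimeras were infected too, all on day 15. Of 18613 wells used, 15533 held at least 1000 transcripts and were kept as cells, with a median of 5326 transcripts and 1712 genes. Tests compared per-animal sums over cells, in CPM (a gene's transcripts relative to its sum's total), and covered 2 mice each for marrow, resting lung and days 4, 7 and 15 of infection. They also covered 8 parabionts, 4 chimera units and 8 culture arms. The limma p-values measure spread between these samples. Groups without separate animals (neonatal, lung progenitor gate, day 10, vessel-labelled and blood cells) give single sums with 95% Poisson intervals, which cover counting error only and have no replicate check.

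Clustering all in vivo cells by variable genes, with proliferation genes left out, gave groups named from marker lists fixed beforehand. ILC2-like cells made up 54.3 ± 26.3% of resting lung cells (SD, n = 2), with 25.9 ± 7.17% T-cell-like and 17.3 ± 19% unnamed. The marrow cells sorted as positive for both Il18r1 and Icos were 76.2 ± 2.8% progenitor-like (SD, n = 2). ILC2-like cells were 75.3 ± 1.99% on day 4, 43.9 ± 20.1% on day 7 and 85.9 ± 5.08% on day 15 (SD, n = 2 each), and many day 7 cells, 45.6 ± 13.8%, stayed unnamed. Clusters were made from the same genes the comparisons test, so these shares describe the cells and are no separate evidence of change.

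The first comparison asked how marrow ILC progenitors (Lin-Il18r1+Icos+) differ from ILCs of resting lung. Most proliferation genes were higher in marrow. Of 23 immediate-early and stress genes, which cells switch on soon after a stimulus, 17 were lower in marrow, as were 6 of 14 ILC2 cytokine genes. Il1rl1, which encodes the receptor for IL-33, was lower in marrow, and Il17rb, which encodes a receptor for IL-25, was higher. Gata3, the transcription factor ILC2 depend on, did not pass.

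With limma and precision weights, 2217 of 12324 genes differed at an adjusted p below 0.05, 1097 higher and 1120 lower in marrow. Of the immediate-early and stress genes, 0 rose, 17 fell and 6 did not pass, or 0 and 18 adjusted over the list alone (median log2 fold change -5.48, limma camera adjusted p = 4.04e-15, adjusted p = 0.169 with an estimated correlation). Junb fell in marrow to 42.9 ± 10.5 against 3354 ± 131 CPM (SD, n = 2 and 2; log2 fold change -6.30, SE 0.29, limma adjusted p = 2.5e-06). Fos stood at 1.27 ± 1.79 against 1335 ± 301 CPM (SD, n = 2 and 2), Atf3 at 0 ± 0 against 186 ± 35.8 CPM and Areg, an epithelial repair factor, at 0.433 ± 0.613 against 742 ± 166 CPM. The regulators Rgs2 (-6.49, SE 0.38, limma adjusted p = 5.82e-06) and Nfkbia (-4.11, SE 0.20, limma adjusted p = 2.85e-06) also fell. Of the proliferation genes, 26 rose, 0 fell and 4 did not pass, or 27 and 0 adjusted over the list alone (median log2 fold change 2.22, limma camera adjusted p = 4.04e-15, adjusted p = 0.354 with an estimated correlation). Mki67, a marker of cycling cells, rose to 253 ± 73.3 against 21.8 ± 5.64 CPM (SD, n = 2 and 2; log2 fold change 3.51, SE 0.43, limma adjusted p = 4.18e-04), and Cdk1 (5.50, SE 1.39, limma adjusted p = 0.0216) and Top2a (3.69, SE 0.44, limma adjusted p = 3.52e-04) rose too.

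Of the ILC2 effector cytokines, 0 rose, 6 fell and 8 did not pass, or 0 and 9 adjusted over the list alone (median log2 fold change -4.45, limma camera adjusted p = 1.01e-04, adjusted p = 0.309 with an estimated correlation). Il5 (-5.88, SE 1.17, limma adjusted p = 0.0073) and Calca, the neuropeptide CGRP (-5.39, SE 0.45, limma adjusted p = 4.83e-05), fell, and Il13 did not pass (-5.31, limma adjusted p = 0.0693). Of the ILC2 identity genes, 2 rose, 8 fell and 11 did not pass (median log2 fold change -0.35, limma camera adjusted p = 0.00213, adjusted p = 0.309 with an estimated correlation). Il1rl1 fell to 139 ± 50.4 against 1042 ± 109 CPM (SD, n = 2 and 2; log2 fold change -2.95, SE 0.20, limma adjusted p = 1.52e-05), as did Klrg1 (-4.43, SE 0.63, limma adjusted p = 0.0011) and Il2ra (-2.19, SE 0.21, limma adjusted p = 1.11e-04), while Il17rb rose (2.02, SE 0.17, limma adjusted p = 4.78e-05). Gata3 (0.14, limma adjusted p = 0.543), Icos (0.01, limma adjusted p = 0.966) and Arg1 (-0.10, limma adjusted p = 0.789) did not pass. With all marrow gates pooled, Gata3 (-0.43) and Icos (-0.88) turned lower. Of the progenitor genes, 6 rose, 4 fell and 11 did not pass, or 9 and 5 adjusted over the list alone (median log2 fold change 0.08, limma camera adjusted p = 0.491, adjusted p = 0.647 with an estimated correlation). Maf (1.25, SE 0.14, limma adjusted p = 2.58e-04) and Tox2 (4.63, SE 0.72, limma adjusted p = 0.00194) rose, while Kit fell (-2.37, SE 0.33, limma adjusted p = 0.00106). Il18r1 stood at 504 ± 8.23 against 161 ± 49.9 CPM (SD, n = 2 and 2; log2 fold change 1.67, SE 0.27, limma adjusted p = 0.00219), but the marrow cells were sorted for Il18r1 and Icos, so the values of these 2 genes follow in part from the gate. Tcf7 (0.88, limma adjusted p = 0.0661) and Zbtb16 (0.84, limma adjusted p = 0.0797), both progenitor transcription factors, did not pass.

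Of the genes tied to inhibition and activation, mostly receptors, 0 rose, 7 fell and 9 did not pass (median log2 fold change -2.84, limma camera adjusted p = 4.74e-05, adjusted p = 0.309 with an estimated correlation). Among them were the receptor gene Tnfrsf18 (-2.70, SE 0.29, limma adjusted p = 1.9e-04) and Dgat1, a lipid-storage enzyme gene on that list (-5.06, SE 0.49, limma adjusted p = 1.22e-04). Of the migration and residency genes, 2 rose, 9 fell and 10 did not pass, or 2 and 11 adjusted over the list alone (median log2 fold change -1.16, limma camera adjusted p = 0.00117, adjusted p = 0.169 with an estimated correlation). Among them was Gpr183 (-1.97, SE 0.23, limma adjusted p = 3.29e-04). Of the interferon-response genes, 6 rose, 0 fell and 11 did not pass, or 7 and 0 adjusted over the list alone (median log2 fold change 0.57, limma camera adjusted p = 0.00768, adjusted p = 0.362 with an estimated correlation). For the ILC3 list 3 rose, 0 fell and 12 did not pass, or 4 and 3 adjusted over the list alone (median log2 fold change -0.04 against a mean of 0.35). For ILC1 and NK genes 1 rose, 1 fell and 16 did not pass, or 0 and 1 adjusted over the list alone, with a median of -0.22 against a mean of 0.24. For T-cell genes 0 rose, 3 fell and 12 did not pass, with Cd3e lower (-1.15, SE 0.33, limma adjusted p = 0.0337), and for MHC class II 1 rose, 0 fell and 8 did not pass, with Cd74 not passing (-1.03, limma adjusted p = 0.398).

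For the glycolysis list 2 rose, 4 fell and 9 did not pass, or 3 and 5 adjusted over the list alone. For basophil and mast cell genes 2 rose, 0 fell and 8 did not pass, and the basophil protease Prss34 stood at 86.7 ± 40.3 against 0 ± 0 CPM (SD, n = 2 and 2). Of B-cell genes, 1 rose, 0 fell and 3 did not pass; of myeloid genes, 1 rose, 0 fell and 9 did not pass, or 0 and 0 adjusted over the list alone. Of erythroid genes, 1 rose, 0 fell and 2 did not pass; of epithelial and endothelial genes, 1 rose, 0 fell and 3 did not pass; of stromal genes, 0 rose, 0 fell and 3 did not pass. None of these 7 lists passed as a set (limma camera adjusted p = 0.191 or higher). Without marrow mouse 1 the count of genes was 610 and without marrow mouse 2 it was 675, against 2217 with both. Lung was digested enzymatically and marrow was crushed.

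**Figure D1:**
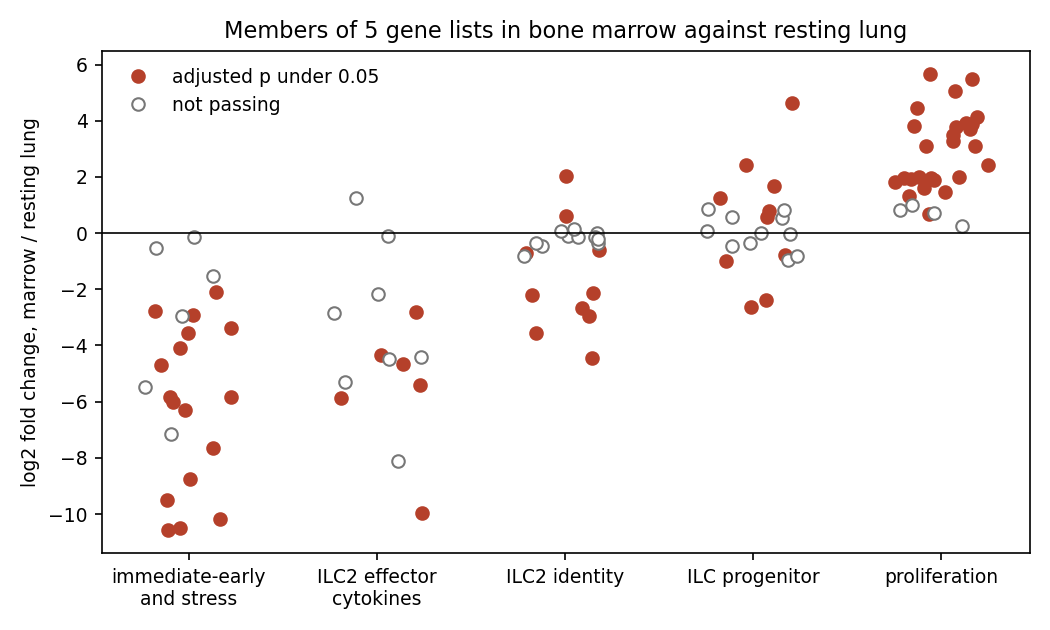
Log2 fold change of list members between Lin-Il18r1+Icos+ marrow cells and resting lung cells (y axis), by gene list (x axis). Each point is 1 gene, fitted on 2 mice per group.

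The 3 marrow gates were compared within the same 2 mice to ask what Il18r1 and Icos mark. In cells with Icos but no Il18r1 the IL-33 receptor gene Il1rl1, the IL-2 receptor gene Il2ra and 4 of 10 basophil genes were higher and Tcf7 was lower, while ILC2 identity genes did not pass as a list. Cells with Il18r1 but no Icos looked like NK cells and basophils, with the granzyme gene Gzma and the protease gene Mcpt8 high and Gata3, Maf and Il17rb low.

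In Lin-Il18r1-Icos+ cells, 103 of 9045 genes differed from the double-positive cells, 68 higher and 35 lower. Il1rl1 rose to 620.4 ± 165 against 169.5 ± 59.5 CPM (SD, n = 2 and 2; log2 fold change 1.88, SE 0.24, limma adjusted p = 0.00408), with Il2ra (1.44, SE 0.21, limma adjusted p = 0.00787) and Ly6a (1.99, SE 0.21, limma adjusted p = 8.46e-04). Il18r1 itself, a gate gene, fell (-1.85, SE 0.14, limma adjusted p = 5.2e-05), as did Tcf7 (-0.94, SE 0.18, limma adjusted p = 0.0239), Cd7 (-1.60, SE 0.19, limma adjusted p = 0.00221) and Mki67 (-1.18, SE 0.22, limma adjusted p = 0.0212). Of the ILC2 identity genes, 3 rose, 2 fell and 16 did not pass, or 4 and 2 adjusted over the list alone (median log2 fold change -0.16, limma camera adjusted p = 0.901, adjusted p = 0.942 with an estimated correlation). Of the progenitor genes, 2 rose, 5 fell and 14 did not pass, or 3 and 8 adjusted over the list alone (median log2 fold change -0.18, limma camera adjusted p = 0.00524, adjusted p = 0.369 with an estimated correlation). Of the basophil genes, 4 rose, 0 fell and 6 did not pass, or 5 and 0 adjusted over the list alone (median log2 fold change 1.34, limma camera adjusted p = 1.12e-07, adjusted p = 0.372 with an estimated correlation), with Mcpt8 higher (2.50, SE 0.43, limma adjusted p = 0.0179). For proliferation 0 rose, 2 fell and 28 did not pass, or 0 and 12 adjusted over the list alone (median log2 fold change -0.53, limma camera adjusted p = 6.37e-10, adjusted p = 0.372 with an estimated correlation). Gata3 (-0.01, limma adjusted p = 0.994), Arg1 (-0.26, limma adjusted p = 0.587), Zbtb16 (-0.60, limma adjusted p = 0.276) and Klrg1 (2.00, limma adjusted p = 0.0783) did not pass. Without the mouse block 7 genes passed.

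In Lin-Il18r1+Icos- cells, 919 of 9045 genes differed from the double-positive cells, 476 higher and 443 lower. Of the NK genes, 16 rose, 0 fell and 0 did not pass (median log2 fold change 3.45, limma camera adjusted p = 3.96e-30, adjusted p = 0.101 with an estimated correlation). Gzma rose to 946 ± 40.3 against 13.6 ± 2.9 CPM (SD, n = 2 and 2; log2 fold change 5.92, SE 0.20, limma adjusted p = 2.97e-09) and Klrd1, an NK receptor gene, rose too (4.63, SE 0.24, limma adjusted p = 9.58e-08). All basophil genes measured rose (10 rose, 0 fell and 0 did not pass; median log2 fold change 4.17, limma camera adjusted p = 6.25e-18, adjusted p = 0.232 with an estimated correlation). Among them were Mcpt8 (5.61, SE 0.43, limma adjusted p = 2.11e-06) and Gata2 (4.84, SE 0.43, limma adjusted p = 8.27e-06). Of the ILC2 identity genes, 0 rose, 18 fell and 3 did not pass, or 0 and 19 adjusted over the list alone (median log2 fold change -1.84, limma camera adjusted p = 5.7e-28, adjusted p = 0.232 with an estimated correlation). Gata3 fell to 274 ± 53.8 against 1396 ± 216 CPM (SD, n = 2 and 2; log2 fold change -2.34, SE 0.14, limma adjusted p = 3e-07), with Il17rb (-4.00, SE 0.18, limma adjusted p = 4.08e-08) and the gate gene Icos (-3.36, SE 0.15, limma adjusted p = 2.83e-08). For proliferation 17 rose, 0 fell and 13 did not pass, or 25 and 0 adjusted over the list alone (median log2 fold change 0.86, limma camera adjusted p = 3.64e-15, adjusted p = 0.232 with an estimated correlation), and Mki67 rose (0.91, SE 0.22, limma adjusted p = 0.0161). Cd74 rose (2.24, SE 0.41, limma adjusted p = 0.00327). Tcf7 (0.26, limma adjusted p = 0.444), Zbtb16 (-0.26, limma adjusted p = 0.582) and Klrg1 (0.33, limma adjusted p = 0.769) did not pass. Of these cells 70.3 ± 7.75% were ILC1/NK-like and 11.1 ± 0.873% basophil-like (SD, n = 2).

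**Figure D2:**
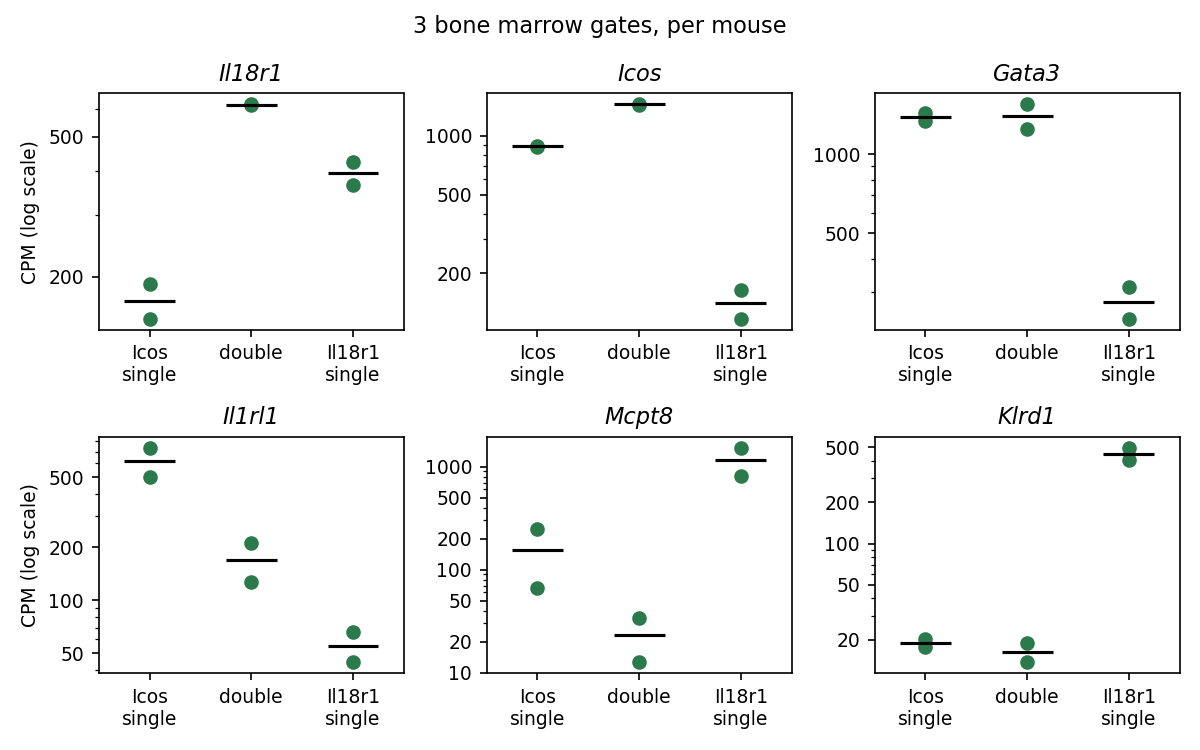
CPM per mouse (y axis) of marker genes in the 3 marrow gates (x axis). Each point is 1 mouse, 2 per gate.

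The infection course asked how lung ILCs change after the helminth. Resting and day 15 libraries carry the same set marks, and day 4 and day 7 libraries carry none. For day 4 and day 7 a difference between sets therefore cannot be told from one between days. On day 4, 5 of 9 genes for presenting antigen on MHC class II rose, as did the cytokine genes Il13 and Csf2 and Arg1, a metabolic enzyme of ILC2. Of 15 T-cell genes 5 fell, Zbtb16 fell, and Il18r1, Icos, S1pr1 and Klf2, the last 2 of which keep lymphocytes circulating, fell as well.

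On day 4, 661 of 12324 genes differed from resting lung, 292 higher and 369 lower. Of the MHC class II genes, 5 rose, 0 fell and 4 did not pass (median log2 fold change 1.68, limma camera adjusted p = 1.47e-04, adjusted p = 0.38 with an estimated correlation), with H2-Aa (3.19, SE 0.41, limma adjusted p = 0.00349) and Cd74 (2.28, SE 0.45, limma adjusted p = 0.0193) among them. Of the cytokines, 3 rose, 0 fell and 11 did not pass, or 4 and 0 adjusted over the list alone, with Il13 (1.54, SE 0.35, limma adjusted p = 0.0326), Csf2 (1.96, SE 0.46, limma adjusted p = 0.0362) and Calca (1.24, SE 0.18, limma adjusted p = 0.0064) higher, and Arg1 rose (0.97, SE 0.22, limma adjusted p = 0.0352). Ccl22, a chemokine that draws T cells, stood at 71.9 ± 37.4 against 0 ± 0 CPM (SD, n = 2 and 2). Of the T-cell genes, 1 rose, 5 fell and 9 did not pass, or 1 and 7 adjusted over the list alone (median log2 fold change -0.82, limma camera adjusted p = 1.47e-04, adjusted p = 0.38 with an estimated correlation). Among them was Cd3e (-2.60, SE 0.38, limma adjusted p = 0.00657). Of the progenitor genes, 3 rose, 5 fell and 13 did not pass, or 3 and 8 adjusted over the list alone: Pdcd1 (1.89, SE 0.20, limma adjusted p = 0.00165) and Ly6a (1.94, SE 0.21, limma adjusted p = 0.00166) rose and Il18r1 (-2.06, SE 0.33, limma adjusted p = 0.0081), Zbtb16 (-2.54, SE 0.41, limma adjusted p = 0.00848) and Tcf7 (-1.78, SE 0.40, limma adjusted p = 0.0312) fell. Icos fell to 442 ± 38.3 against 1172 ± 189 CPM (SD, n = 2 and 2; log2 fold change -1.40, SE 0.16, limma adjusted p = 0.0019), and S1pr1 (-2.40, SE 0.35, limma adjusted p = 0.00668) and Mki67 (-1.98, SE 0.38, limma adjusted p = 0.0188) fell. Il5 (0.45, limma adjusted p = 0.552), Areg (0.29, limma adjusted p = 0.68), Gata3 (0.48, limma adjusted p = 0.0953), Il1rl1 (0.69, limma adjusted p = 0.0761) and Klrg1 (1.01, limma adjusted p = 0.116) did not pass. The count was 70 without infected mouse 1, 60 without infected mouse 2 and 45 without resting mouse 1. Hspa1a, a heat-shock gene, was at 479.9 and 893 CPM in the day 4 mice against 41.3 and 63 in resting mice.

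On day 7 Gzma and Il1r2, a decoy receptor for IL-1, rose, with 5 of 9 MHC class II and 8 of 30 proliferation genes. The checkpoint gene Ctla4 and the transcription factor gene Irf4 also rose. Zbtb16, Icos and Il18r1 fell, and so did 7 of 15 T-cell and 9 of 23 immediate-early genes.

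On day 7, 1211 of 12324 genes differed from resting lung, 504 higher and 707 lower. Gzma rose to 332 ± 209.9 against 0.723 ± 0.658 CPM (SD, n = 2 and 2; log2 fold change 7.81, SE 0.89, limma adjusted p = 0.00137), with Il1r2 (4.77, SE 0.55, limma adjusted p = 0.00137), Irf4 (3.25, SE 0.42, limma adjusted p = 0.00195) and Ctla4 (3.07, SE 0.56, limma adjusted p = 0.00905). Of the MHC class II genes, 5 rose, 0 fell and 4 did not pass, or 6 and 0 adjusted over the list alone (median log2 fold change 2.25, limma camera adjusted p = 1.29e-05, adjusted p = 0.317 with an estimated correlation). Among them was Cd74 (2.97, SE 0.45, limma adjusted p = 0.00382). Of the proliferation genes, 8 rose, 0 fell and 22 did not pass, or 10 and 0 adjusted over the list alone (median log2 fold change 1.29, limma camera adjusted p = 1.89e-06, adjusted p = 0.586 with an estimated correlation). Among them was Mki67 (1.82, SE 0.38, limma adjusted p = 0.0156). Il13 (1.88, SE 0.35, limma adjusted p = 0.00936), Arg1 (696 ± 96.5 against 317 ± 65.4 CPM, SD, n = 2 and 2) and Klrg1 (1.46, SE 0.35, limma adjusted p = 0.0272) rose. Of the T-cell genes, 0 rose, 7 fell and 8 did not pass, or 1 and 12 adjusted over the list alone (median log2 fold change -1.35, limma camera adjusted p = 2.38e-07, adjusted p = 0.317 with an estimated correlation). Among them was Cd3e (-3.55, SE 0.38, limma adjusted p = 0.00109). Of the immediate-early genes, 0 rose, 9 fell and 14 did not pass, or 0 and 12 adjusted over the list alone (median log2 fold change -0.80, limma camera adjusted p = 1.13e-06, adjusted p = 0.317 with an estimated correlation). Among them was Junb (-1.30, SE 0.21, limma adjusted p = 0.00561). Zbtb16 (-2.97, SE 0.41, limma adjusted p = 0.00265), Il18r1 (-1.64, SE 0.33, limma adjusted p = 0.0125) and Icos (-1.30, SE 0.16, limma adjusted p = 0.00147) fell. Il5 (-0.21, limma adjusted p = 0.777), Areg (-0.47, limma adjusted p = 0.453), Gata3 (0.05, limma adjusted p = 0.883), Il1rl1 (0.45, limma adjusted p = 0.189) and Tcf7 (-0.90, limma adjusted p = 0.168) did not pass. The count was 2243 without infected mouse 1, 382 without infected mouse 2 and 237 without resting mouse 1. Transcripts of unannotated Gm genes made up 26.4% and 43.2% in the day 7 mice against 22.3% and 16.2% in resting mice. Immediate-early and stress genes summed to 11249 and 5709 CPM in the day 7 mice. They summed to 16239 and 19284 CPM in resting mice and to 15096 and 14470 CPM in day 15 mice.

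On day 15 Il13, Il1rl1, Klrg1, Arg1 and 6 of 9 MHC class II genes rose together with the co-stimulatory and checkpoint genes Tnfrsf4, Ctla4 and Pdcd1. Il6 and Il1r2 rose too, and 8 of 15 T-cell and 6 of 15 ILC3 genes fell.

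On day 15, 597 of 12324 genes differed from resting lung, 378 higher and 219 lower. Il13 rose to 1114 ± 159 against 84.9 ± 4.43 CPM (SD, n = 2 and 2; log2 fold change 3.70, SE 0.35, limma adjusted p = 6.32e-04), and Il6 rose (3.42, SE 0.66, limma adjusted p = 0.0143). Of the cytokine genes, 4 rose, 0 fell and 10 did not pass, or 7 and 0 adjusted over the list alone (median log2 fold change 0.83, limma camera adjusted p = 0.0129, adjusted p = 0.4 with an estimated correlation). Il1rl1 (1.18, SE 0.21, limma adjusted p = 0.00885), Klrg1 (2.11, SE 0.35, limma adjusted p = 0.00675) and Arg1 (887 ± 24.6 against 317 ± 65.4 CPM, SD, n = 2 and 2) rose. For ILC2 identity 6 rose, 4 fell and 11 did not pass, or 8 and 4 adjusted over the list alone (median log2 fold change 0.05, limma camera adjusted p = 0.219, adjusted p = 0.508 with an estimated correlation). Of the MHC class II genes, 6 rose, 0 fell and 3 did not pass, or 7 and 0 adjusted over the list alone (median log2 fold change 3.03, limma camera adjusted p = 3.82e-11, adjusted p = 0.189 with an estimated correlation), and Cd74 rose to 687 ± 135 against 36.5 ± 21.8 CPM (SD, n = 2 and 2; log2 fold change 4.33, SE 0.45, limma adjusted p = 7.43e-04). Of the inhibition and activation genes, 5 rose, 1 fell and 10 did not pass, or 8 and 1 adjusted over the list alone (median log2 fold change 0.89, limma camera adjusted p = 5.75e-06, adjusted p = 0.194 with an estimated correlation), with Tnfrsf4 (4.39, SE 0.67, limma adjusted p = 0.00434) and Ctla4 (4.07, SE 0.56, limma adjusted p = 0.00235). Il1r2 rose (6.74, SE 0.55, limma adjusted p = 3.24e-04), as did Mki67 (1.89, SE 0.38, limma adjusted p = 0.018). Of the proliferation genes, 5 rose, 0 fell and 25 did not pass, or 7 and 0 adjusted over the list alone (limma camera adjusted p = 3.43e-09, adjusted p = 0.404 with an estimated correlation).

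Of the T-cell genes on day 15, 0 rose, 8 fell and 7 did not pass, or 0 and 10 adjusted over the list alone (median log2 fold change -2.03, limma camera adjusted p = 7.59e-10, adjusted p = 0.189 with an estimated correlation). Among them was Cd3e (-3.47, SE 0.38, limma adjusted p = 8.15e-04). Of the ILC3 genes, 0 rose, 6 fell and 9 did not pass (median log2 fold change -0.41, limma camera adjusted p = 1.35e-05, adjusted p = 0.194 with an estimated correlation). Among them was Tmem176a (-2.21, SE 0.24, limma adjusted p = 7.72e-04). Of the glycolysis genes, 3 rose, 0 fell and 12 did not pass, or 6 and 0 adjusted over the list alone (median log2 fold change 0.52, limma camera adjusted p = 1e-04, adjusted p = 0.242 with an estimated correlation), with Ldha higher (0.76, SE 0.17, limma adjusted p = 0.0305). Zbtb16 (-2.52, SE 0.41, limma adjusted p = 0.00576) and Icos (-0.62, SE 0.16, limma adjusted p = 0.0463) fell. Il5 (1.15, limma adjusted p = 0.174), Areg (1.05, limma adjusted p = 0.162), Gata3 (0.52, limma adjusted p = 0.0934), Il18r1 (-0.62, limma adjusted p = 0.36) and Tcf7 (-0.56, limma adjusted p = 0.55) did not pass. Without day 15 mouse 3 the count was 116, without day 15 mouse 4 it was 265, and without resting mice 1 and 2 it was 233 and 160.

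From day 7 to day 15 Gzma and Nmur1, the receptor gene for the neuropeptide neuromedin U, fell, and Il13, Areg and 6 of 23 immediate-early genes rose. Gzma stayed above resting lung. Dgat1, a lipid-storage enzyme gene, the integrin gene Itgae and the inflammasome gene Nlrp3 rose. Day 7 libraries lack the set marks of the day 15 libraries, so these changes may in part be differences between sets.

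Between these days 1004 of 12324 genes differed, 739 higher and 265 lower on day 15. Il13 (1.82, SE 0.35, limma adjusted p = 0.011), Areg (1.52, SE 0.38, limma adjusted p = 0.0334), Dgat1 (3.08, SE 0.27, limma adjusted p = 2.82e-04) and Itgae (2.61, SE 0.34, limma adjusted p = 0.00197) rose. Of the immediate-early genes, 6 rose, 0 fell and 17 did not pass, or 8 and 1 adjusted over the list alone (median log2 fold change 0.50, limma camera adjusted p = 0.00217, adjusted p = 0.331 with an estimated correlation). Among them was Junb (1.30, SE 0.21, limma adjusted p = 0.00533). Of the inhibition and activation genes, 6 rose, 0 fell and 10 did not pass, or 7 and 1 adjusted over the list alone (median log2 fold change 0.86, limma camera adjusted p = 0.00396, adjusted p = 0.331 with an estimated correlation). Gzma (-3.48, SE 0.89, limma adjusted p = 0.0363) and Nmur1 (-2.49, SE 0.33, limma adjusted p = 0.00197) fell. On day 15 Gzma was still above resting lung (4.33, limma adjusted p = 0.0189), at 7.61 and 85.7 CPM in the 2 mice, and Nmur1 below it (-1.76, limma adjusted p = 0.0106). For NK genes 0 rose, 2 fell and 16 did not pass, or 2 and 7 adjusted over the list alone (median log2 fold change -1.45, limma camera adjusted p = 0.00217, adjusted p = 0.458 with an estimated correlation). Icos rose (0.67, SE 0.16, limma adjusted p = 0.0252), and Mki67 (0.07, limma adjusted p = 0.936), Il5 (1.36, limma adjusted p = 0.0735), Cd74 (1.36, limma adjusted p = 0.0864), Il18r1 (1.02, limma adjusted p = 0.0778) and Il1rl1 (0.73, limma adjusted p = 0.0534) did not pass. Without day 15 mouse 3 the count was 99 and without day 15 mouse 4 it was 290; without day 7 mouse 1 it was 1660 and without day 7 mouse 2 it was 387. The unannotated Gm10800 stood at 68727 ± 578 against 315179 ± 186846 CPM (SD, n = 2 and 2).

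**Figure D3:**
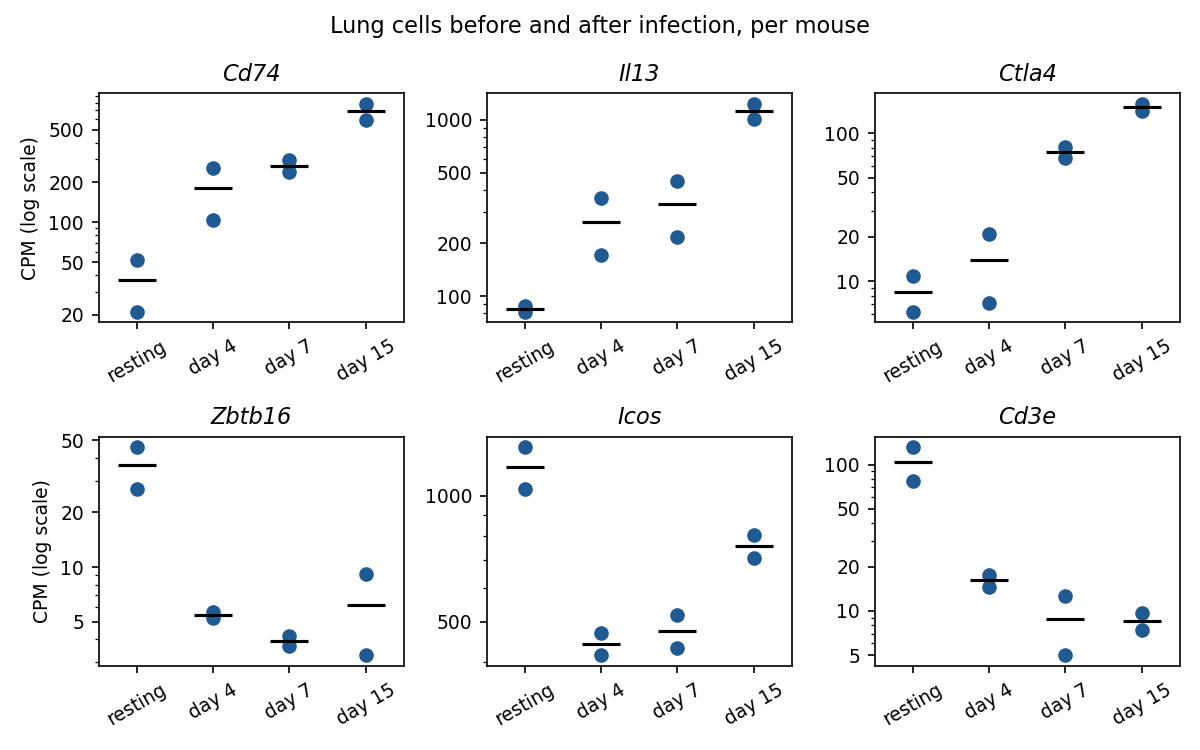
CPM per mouse (y axis) of panel and list genes in resting lung and on days 4, 7 and 15 of infection (x axis). Each point is 1 mouse, 2 per group.

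On day 10 of infection, a single sum of 348 cells carried MHC class II and proliferation genes above resting lung and T-cell genes below it. MHC class II genes were higher (median log2 ratio 3.09, 6 of 8 higher, percentile 100 among 10000 random lists), with H2-Ab1 19.4-fold and Cd74 9.54-fold higher. Proliferation genes were higher too (median log2 ratio 1.98, 28 of 30 higher, percentile 100) and T-cell genes lower (median log2 ratio -2.36, 0 of 14 higher, percentile 0). Il1r2 was 50.5-fold and Il13 2.72-fold higher, and Gzma at least 313-fold higher. The cytokine list as a whole was lower (median log2 ratio -1.23, 4 of 13 higher, percentile 0.95), with Areg 2.92-fold and Calca 2.34-fold lower. Zbtb16 was 15.7-fold, Il18r1 9.19-fold and Icos 5-fold lower. Unannotated genes made up 47.5% of its transcripts, and the median log2 ratio of all 10440 genes with at least 5 CPM was -0.49, so lower folds here are overstated and higher ones understated.

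Day 10 cells reached by an intravenous CD45 antibody, and so within vessels, had more of the recirculation genes S1pr1 and Klf2 than the other day 10 cells. S1pr1 was at 103 CPM (95% 91.2 to 116) against 23.2 (17.7 to 29.7) and Klf2 was 3.64-fold higher. Klrg1 was 2.21-fold and Itga4, a homing integrin gene, 3.25-fold higher. Interferon-response genes were higher (median log2 ratio 1.08, 10 of 11 higher, percentile 100) and proliferation genes lower (median log2 ratio -0.42, 6 of 30 higher, percentile 0). Il1r2 was 3.5-fold, Bcl2 5.07-fold and Il1rl1 1.53-fold lower.

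Blood cells taken on day 15 had more of the recirculation genes Klf2 and S1pr1 than day 15 lung cells. They had far less of the cytokine and immediate-early genes. Klf2 was at 323 CPM (95% 299.5 to 348) against 24.4 (15.2 to 34.8), and S1pr1 was 6.34-fold higher. The migration and residency list as a whole was lower (median log2 ratio -0.70, 8 of 21 higher, percentile 0.24). Cytokine genes were lower (median log2 ratio -4.10, 0 of 13 higher, percentile 0), with Il13 33.6-fold, Il5 11.2-fold and Areg 144-fold lower. Immediate-early genes were lower (median log2 ratio -3.61, 0 of 23 higher, percentile 0), and so were Icos (4.76-fold) and Il1rl1 (3.65-fold). T-cell genes were higher (median log2 ratio 2.18, 11 of 14 higher, percentile 100), with Cd3e 8.46-fold higher, and erythroid genes reached 2803 CPM.

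Neonatal lung (postnatal day 4) was sorted by ST2, the protein of Il1rl1. ST2-positive cells had more of the ILC2 genes, and ST2-negative cells had more of the progenitor and NK genes and of the markers of several other cell types. Csf2, which encodes GM-CSF, was at 578 CPM (95% 541 to 616) against 20 (13.7 to 28.3) and Klrg1 18.5-fold, Areg 8.36-fold, Il13 6.92-fold and Gata3 3.05-fold higher in ST2-positive cells. In ST2-negative cells Tcf7 was 21-fold, Cd7 37.5-fold and Il18r1 10.2-fold higher. Zbtb16 was at 3.71 CPM (95% 1.36 to 8.07) against 113 (97.4 to 131) in ST2-positive against ST2-negative cells. ILC2 cytokine genes (median log2 ratio 2.13, 11 of 12 higher, percentile 100) and NK genes (median log2 ratio -4.19, 0 of 16 higher, percentile 0) lay at opposite ends. Also lower in ST2-positive cells were progenitor (median log2 ratio -1.56, 2 of 22 higher, percentile 0), B-cell (median log2 ratio -2.02, 0 of 7 higher, percentile 0), myeloid (median log2 ratio -1.52, 1 of 10 higher, percentile 0.02), basophil and mast cell (median log2 ratio -1.89, 2 of 9 higher, percentile 0) and ILC3 genes (median log2 ratio -1.43, 2 of 13 higher, percentile 0.01). Against resting adult lung, proliferation genes were higher in ST2-positive (median log2 ratio 2.44, 30 of 30 higher, percentile 100) and ST2-negative cells (median log2 ratio 2.85, 30 of 30 higher, percentile 100), with Mki67 13.9-fold and 18.2-fold higher.

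Adult lung cells sorted with the progenitor gate (Il18r1+Icos+ST2-Il17rb-) had less of the ILC2 genes and more of the T-cell, B-cell and MHC class II genes than resting lung ILCs. Gata3 was 3.54-fold and Calca 69.9-fold lower. Il1rl1, whose protein the sort excluded, was at 19.7 CPM (95% 12.3 to 29.8) against 1063 (934 to 1200). Tcf7 was 2.27-fold and Cd3e 2.36-fold higher. ILC2 identity genes were lower (median log2 ratio -1.75, 1 of 21 higher, percentile 0), T-cell genes higher (median log2 ratio 0.46, 12 of 14 higher, percentile 100) and MHC class II genes higher (median log2 ratio 2.16, 7 of 8 higher, percentile 100). B-cell genes, whose cells also carry MHC class II, were higher too (median log2 ratio 2.89, 6 of 7 higher, percentile 100; 4 at a bound). T-cell-like cells made up 49.1% of this sort. The median log2 ratio of all genes with at least 5 CPM was -0.42 against resting lung and -0.68 against marrow, overstating lower folds and understating higher ones. Against the marrow double-positive cells, proliferation genes were lower (median log2 ratio -2.56, 0 of 30 higher, percentile 0), with Mki67 9.45-fold lower. Il17rb, a gate gene here, was 10.3-fold lower. Immediate-early genes were higher (median log2 ratio 4.01, 20 of 21 higher, percentile 100), with Jun 101-fold higher and 7 members at a bound.

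In parabionts, lung cells from the partner (donor) were set against the animal's own cells (host) to ask what cells that arrive through blood lack or carry. Donor cells had less of the ILC2 program: the IL-33 receptor gene Il1rl1, Gata3, Arg1, Areg and Calca were lower. They had more of Klf2 and S1pr1, which circulating lymphocytes and endothelial cells both carry, and less Ccr2, a chemokine receptor gene.

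Over 8 animals, 160 of 10805 genes differed, 41 higher and 119 lower in donor cells. Il1rl1 fell to 260 ± 97.8 against 530.3 ± 119.6 CPM (SD, n = 8; log2 fold change -1.08, SE 0.13, limma adjusted p = 0.00177; lower in 8 of 8 animals), and Gata3 fell in 8 of 8 (-0.72, SE 0.11, limma adjusted p = 0.0042). Of the ILC2 identity genes, 0 rose, 8 fell and 13 did not pass, or 0 and 15 adjusted over the list alone (median log2 fold change -0.44, limma camera adjusted p = 2.47e-16, adjusted p = 0.04 with an estimated correlation). Among them was Ptpn13 (-0.72, SE 0.13, limma adjusted p = 0.0142). Of the cytokines, 0 rose, 4 fell and 9 did not pass, or 0 and 9 adjusted over the list alone (median log2 fold change -0.74, limma camera adjusted p = 6.67e-10, adjusted p = 0.04 with an estimated correlation). Among them were Calca (52.7 ± 25.3 against 117 ± 60.5 CPM, SD, n = 8) and Areg (-0.86, SE 0.14, limma adjusted p = 0.00693). Il5 (-0.89, limma adjusted p = 0.0532) and Il13 (-0.35, limma adjusted p = 0.496) did not pass. Arg1 (-0.88, SE 0.19, limma adjusted p = 0.0378) and Hs3st1, a heparan sulfate enzyme gene (-1.67, SE 0.14, limma adjusted p = 2.8e-05), fell. Klf2 rose to 75 ± 9.08 against 32.5 ± 19 CPM (SD, n = 8; log2 fold change 1.37, SE 0.22, limma adjusted p = 0.00693), with S1pr1 (1.29, SE 0.25, limma adjusted p = 0.0203) and Satb1 (0.54, SE 0.11, limma adjusted p = 0.03). Klf2 was 0.71 in experiment 1, where it did not pass (limma adjusted p = 0.164), and 2.03 in experiment 2, and epithelial and endothelial genes were higher as a list only at a fixed correlation (adjusted p = 0.066 with an estimated one), with 0 of 14 members passing. Without clusters named as other than ILC, Klf2 (1.28, limma adjusted p = 0.00134) and S1pr1 (1.34, limma adjusted p = 0.0101) still passed. That step kept unnamed cells, and none of the classes it removed from the parabionts was named epithelial or endothelial. At clustering resolution 0.5 cells so named were 1.49 ± 1.32% of donor and 0.509 ± 0.502% of host cells (SD, n = 8). The step therefore cannot show that endothelial or NK-like cells play no part. S1pr1 did not pass without the CD45.2 host of pair 2 in experiment 1 (limma adjusted p = 0.0702) or in experiment 2 (limma adjusted p = 0.0926). Of the migration genes, 4 rose, 5 fell and 13 did not pass, or 5 and 7 adjusted over the list alone, with Ccr2 lower (-0.96, SE 0.11, limma adjusted p = 0.00109).

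Of the immediate-early genes in donor cells, 0 rose, 6 fell and 17 did not pass, or 1 and 8 adjusted over the list alone (median log2 fold change -0.07, limma camera adjusted p = 3.22e-04, adjusted p = 0.308 with an estimated correlation). Among them was Nfkbiz (-0.63, SE 0.09, limma adjusted p = 0.00279). For NK genes 1 rose, 0 fell and 16 did not pass, or 4 and 0 adjusted over the list alone (median log2 fold change 0.52, limma camera adjusted p = 7.26e-05, adjusted p = 0.22 with an estimated correlation). For T-cell genes 1 rose, 0 fell and 13 did not pass, or 3 and 0 adjusted over the list alone (median log2 fold change 0.31, limma camera adjusted p = 0.0206, adjusted p = 0.402 with an estimated correlation). For epithelial and endothelial genes 0 rose, 0 fell and 14 did not pass, or 8 and 0 adjusted over the list alone (median log2 fold change 0.95, limma camera adjusted p = 5.57e-07, adjusted p = 0.066 with an estimated correlation). Icos (-0.12, limma adjusted p = 0.696), Klrg1 (-0.32, limma adjusted p = 0.215), Il18r1 (0.37, limma adjusted p = 0.279), Tcf7 (0.61, limma adjusted p = 0.0926), Zbtb16 (-0.08, limma adjusted p = 0.937), Cd74 (0.28, limma adjusted p = 0.381) and Mki67 (-0.35) did not pass. ILC2-like cells were 24.7 ± 19% of donor and 46.6 ± 14.1% of host cells (SD, n = 8; exact two-sided sign-flip permutation p = 0.0156, adjusted p = 0.0703), lower in 7 of 8 animals. T-cell-like cells were 7.59 ± 4.8% and 2.2 ± 1.37% (SD, n = 8; same exact test, p = 0.00781, adjusted p = 0.0703). The ILC2-like difference of -21.9 points became -4.24 at clustering resolution 0.5, -9.08 at 1.5 and -7.85 with cells of at least 2000 transcripts, and the T-cell-like difference of 5.39 became 0.738 at 0.5. Within ILC2-like cells alone 12 genes passed. The 8 animals form 4 pairs that exchange cells. Summed by pair, 37 genes passed, with Il1rl1 (-1.10, limma adjusted p = 0.0431) and Calca still passing and Gata3 (-0.79, limma adjusted p = 0.0561), Klf2 (1.26, limma adjusted p = 0.0792), S1pr1, Arg1, Areg and Ccr2 no longer passing. With 4 pairs the exact test of shares could not go below 0.125. Leaving out 1 animal of pair 2 in experiment 1 gave 57 genes (CD45.1 host) and 67 (CD45.2 host), and of pair 2 in experiment 2 it gave 75 (CD45.1 host) and 42 (CD45.2 host).

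**Figure D4:**
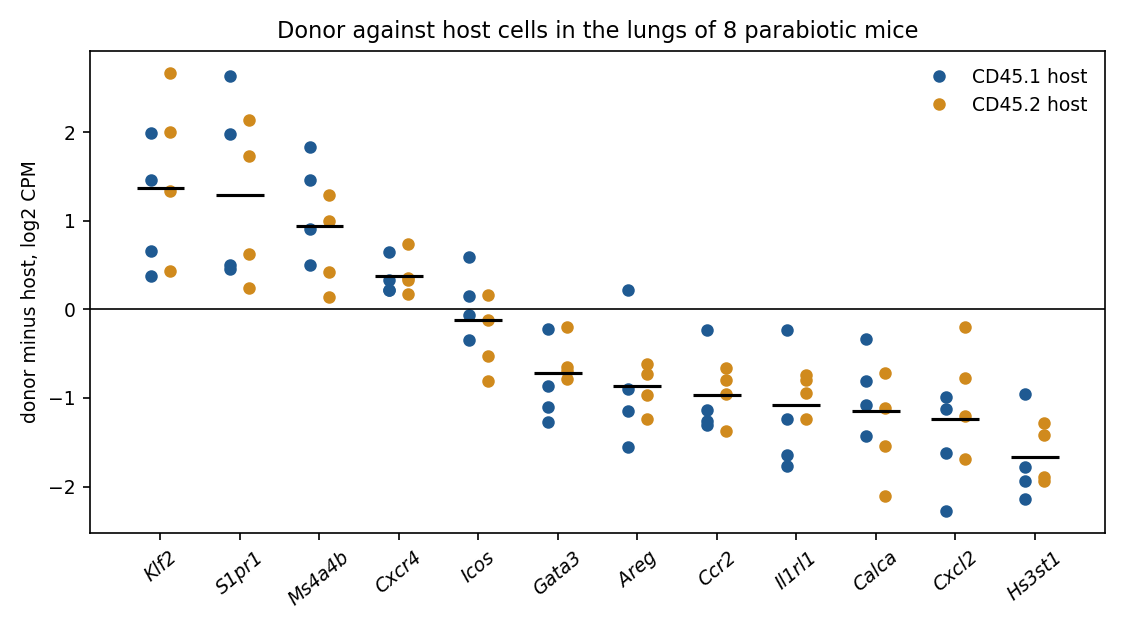
Donor minus host log2 CPM (y axis) for 12 genes (x axis) in parabiont lung. Each point is 1 of 8 animals.

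All cells of CD45.1 host animals, own and partner cells pooled, were compared with those of CD45.2 host animals. Both alleles are mixed on each side, so this speaks of the host animal and not of the allele of the cells. With 4 animals on each side, 0 of 11451 genes passed; 814 had a raw p below 0.05, and with voom weights 0 passed and 883 did. Il1rl1 (-0.09, limma adjusted p = 0.975), Gata3 (0.09, limma adjusted p = 0.97) and Zbtb16 (-0.52, limma adjusted p = 0.807) did not pass. As lists, epithelial and endothelial genes were higher in CD45.1 hosts (median log2 fold change 1.60, limma camera adjusted p = 3.09e-05, adjusted p = 0.757 with an estimated correlation) and myeloid genes lower (median log2 fold change -0.59, limma camera adjusted p = 2.31e-05, adjusted p = 0.757 with an estimated correlation), with no member passing. Epithelial and endothelial genes reached 5511 CPM in 1 animal.

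In shield chimeras, where donor cells sit beside host cells in the lung, the comparison asked what separates the 2 origins. In donor cells 2 of 9 MHC class II genes were higher and Cd3g was lower. The units follow library titles, which do not map one to one onto the animals named in the wells, so they may not be 4 animals. Over 4 units, 11 of 10045 genes differed, 8 higher and 3 lower in donor cells. Cd74 rose to 388 ± 188 against 218 ± 119 CPM (SD, n = 4; log2 fold change 0.88, SE 0.11, limma adjusted p = 0.019), with H2-Aa (0.94, SE 0.14, limma adjusted p = 0.0341), Stab2, an ILC2 identity gene (1.12, SE 0.14, limma adjusted p = 0.019), and Aldh2 (1.13, SE 0.15, limma adjusted p = 0.019), and Cd3g fell (-1.57, SE 0.18, limma adjusted p = 0.0148). Of the MHC class II genes, 2 rose, 0 fell and 7 did not pass, or 5 and 0 adjusted over the list alone (median log2 fold change 0.69, limma camera adjusted p = 1.97e-10, adjusted p = 0.11 with an estimated correlation). For NK genes 0 rose, 0 fell and 10 did not pass, or 5 and 0 adjusted over the list alone (median log2 fold change 0.88, limma camera adjusted p = 1.3e-06, adjusted p = 0.11 with an estimated correlation). For ILC3 genes 0 rose, 0 fell and 9 did not pass, or 6 and 0 adjusted over the list alone (median log2 fold change 0.84, limma camera adjusted p = 4.3e-08, adjusted p = 0.11 with an estimated correlation). For ILC2 identity 1 rose, 0 fell and 20 did not pass, or 4 and 1 adjusted over the list alone. Il1rl1 (-0.26, limma adjusted p = 0.217), Gata3 (0.04, limma adjusted p = 0.891), Il13 (-0.02, limma adjusted p = 0.981), Areg (-0.66, limma adjusted p = 0.141), Arg1 (-0.41, limma adjusted p = 0.546) and Il18r1 (0.93, limma adjusted p = 0.0848) did not pass. The averages of Areg and Arg1 hide a difference between experiments, in a test chosen after the results were seen. Areg was at -0.112 and -0.351 in the units of experiment 2 against -0.996 and -1.17 in experiment 1 (limma adjusted p = 0.0246 for the difference). Arg1 was at -1.11 and -0.903 against 0.0921 and 0.271 (limma adjusted p = 0.00235). The count was 75 and 2 without the first and second unit of experiment 2, 2 and 1 without those of experiment 1, 5 with sums by animal of the well names and 188 with voom weights. It was 0 with thinned cells (365 raw p below 0.05) and 1 in ILC2-like cells.

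Progenitors from lung and marrow were cultured on OP9 stroma, with or without the Notch ligand DL1 and with or without IL-18, 1 library sum per arm. With IL-18 Mme, Fabp5 and H2-Ab1 rose, and the cytokine genes Il13 and Il5 did not pass. Over 4 arms against 4, 82 of 8083 genes differed, 75 higher and 7 lower. Mme, a peptidase gene (2.31, SE 0.23, limma adjusted p = 0.00468), Fabp5, a fatty acid binding protein gene (2.03, SE 0.37, limma adjusted p = 0.0291), and H2-Ab1 (2.04, SE 0.28, limma adjusted p = 0.00952) rose, and F2r, a thrombin receptor gene, fell (-1.59, SE 0.29, limma adjusted p = 0.0291). Il13 (0.29, limma adjusted p = 0.862), Il5 (0.36, limma adjusted p = 0.923), Tcf7 (-1.37, limma adjusted p = 0.186), Il18r1 (-1.26, limma adjusted p = 0.277) and Gata3 (-0.42, limma adjusted p = 0.587) did not pass. For glycolysis 0 rose, 0 fell and 15 did not pass (median log2 fold change 0.36, limma camera adjusted p = 1.14e-05, adjusted p = 0.682 with an estimated correlation), and for ILC2 identity 0 rose, 0 fell and 19 did not pass, or 0 and 1 adjusted over the list alone (median log2 fold change -0.42, limma camera adjusted p = 0.00998, adjusted p = 0.682 with an estimated correlation). Without the marrow arm on OP9 with IL-18 the count was 0 with limma (727 raw p below 0.05), and without the marrow arm on DL1 without IL-18 it was 19. Without the lung arms it was 31 (DL1, with IL-18), 30 (OP9, without) and 10 (OP9, with). Unannotated genes made up 17% to 37.3% of transcripts in arms with IL-18 and 12% to 26% in arms without.

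With the Notch ligand on the stroma, 2 of 9 T-cell and 3 of 6 ILC3 genes rose and 7 of 15 interferon-response genes fell, and none of these lists passed with an estimated correlation. Gimap3, a lymphocyte GTPase gene, Thy1, Cd3g, Ifng, Tnfrsf9 and the glucose transporter gene Slc2a3 rose. With DL1, 161 of 8083 genes differed, 100 higher and 61 lower. Gimap3 (3.67, SE 0.31, limma adjusted p = 2.17e-04), Tnfrsf9 (3.19, SE 0.34, limma adjusted p = 0.00112), H2-Ab1 (3.18, SE 0.28, limma adjusted p = 2.88e-04), Thy1 (2.43, SE 0.42, limma adjusted p = 0.0154) and Ifng (3.27, SE 0.72, limma adjusted p = 0.0441) rose. Of the interferon-response genes, 0 rose, 7 fell and 8 did not pass, or 0 and 10 adjusted over the list alone (median log2 fold change -2.22, limma camera adjusted p = 1.89e-09, adjusted p = 0.0801 with an estimated correlation). Among them were Ifit1 (-4.14, SE 0.29, limma adjusted p = 1.12e-04) and Isg15 (-2.37, SE 0.28, limma adjusted p = 0.00186). Of the glycolysis genes, 3 rose, 0 fell and 12 did not pass, or 12 and 0 adjusted over the list alone (median log2 fold change 0.65, limma camera adjusted p = 1.89e-09, adjusted p = 0.219 with an estimated correlation). Among them was Slc2a3 (2.86, SE 0.40, limma adjusted p = 0.00594). Of the ILC3 genes, 3 rose, 0 fell and 3 did not pass (median log2 fold change 1.41, limma camera adjusted p = 1.21e-05, adjusted p = 0.114 with an estimated correlation). Among them were Lta (2.07, SE 0.40, limma adjusted p = 0.0251) and Tmem176b (1.82, SE 0.27, limma adjusted p = 0.00789). Of the T-cell genes, 2 rose, 0 fell and 7 did not pass, or 3 and 0 adjusted over the list alone (median log2 fold change 1.44, limma camera adjusted p = 1.75e-05, adjusted p = 0.0801 with an estimated correlation). Among them was Cd3g (2.43, SE 0.42, limma adjusted p = 0.0155). Gata3 (-1.04, limma adjusted p = 0.0508) and Il13 (-0.39, limma adjusted p = 0.66) did not pass. The count was 63 without the marrow arm on OP9 with IL-18. Without the lung arms it was 42 (DL1, without IL-18), 98 (OP9, without) and 52 (OP9, with). Stromal genes, 1 rose, 0 fell and 3 did not pass, or 2 and 0 adjusted over the list alone, reached 1503 CPM in the marrow arm with DL1 and IL-18.

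Cultures begun from lung and from marrow differed in 12 of 8083 genes, 3 higher and 9 lower from lung. Cd3e, a T-cell receptor gene, rose (5.13, SE 0.77, limma adjusted p = 0.0375), with Ifit1 (2.42, SE 0.29, limma adjusted p = 0.0102) and Maf (1.20, SE 0.19, limma adjusted p = 0.0375). The motor protein gene Myo6 (-3.18, SE 0.32, limma adjusted p = 0.00469), the cytokine gene Lif (-1.69, SE 0.19, limma adjusted p = 0.00767) and the glycolysis gene Gapdh (-1.16, SE 0.16, limma adjusted p = 0.0239) fell. Of the glycolysis genes, 0 rose, 2 fell and 13 did not pass, or 0 and 13 adjusted over the list alone (median log2 fold change -0.84, limma camera adjusted p = 1.91e-12, adjusted p = 0.214 with an estimated correlation), and of the cytokines, 0 rose, 1 fell and 11 did not pass, or 0 and 3 adjusted over the list alone (median log2 fold change -0.99, limma camera adjusted p = 0.00114, adjusted p = 0.214 with an estimated correlation). Il13 did not pass (-1.69, limma adjusted p = 0.0871). Without the lung arms the count was 0 (DL1, without IL-18), 5 (DL1, with), 78 (OP9, without) and 4 (OP9, with), and without the marrow arms on DL1 and on OP9, both without IL-18, it was 6 and 19. In single cultures from the ST2-Il17rb- gate, 150 cells from lung had Il13 at 295 CPM (95% 256 to 338) against 27.9 (12.8 to 53) in 67 cells from marrow. Calca was 12.3-fold and Icos 4.64-fold higher from lung, and Klf2 4.11-fold lower. Cytokine genes as a list were higher there (median log2 ratio 1.80, 8 of 10 higher, percentile 100 among 10000 random lists, 3 members at a bound).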

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

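The test of Il18r1 alone, the interaction terms and the counts over other splits of the parabiont, chimera, host and culture comparisons were tests chosen only after the results were seen.

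The 17 immediate-early genes called lower in marrow than in resting lung had a median log2 fold change of -5.84. Cells of other types in the lung sort were argued against, since without clusters named as other than ILC the median over the 17 genes was -6.02. Enzymatic digestion of lung may be a cause: blood cells, for which the labels describe no digestion, had a median log2 ratio to day 15 lung of -3.61, with 16 of the 17 genes below -1. Vessel-labelled cells taken from digested lung had a median of 0.56 against other day 10 lung cells, with 1 gene below -1. The tissue itself separates the groups in both contrasts and stays open, untested.

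The 12 ILC2 genes called lower in donor cells of parabionts had a median log2 fold change of -0.87. Within ILC2-like cells the median was -0.51, with 11 of 12 genes lower and 3 still called (range -1.45 to 0.09). A different mix of cell classes may account for part or all of the difference. As many CD45.1 as CD45.2 hosts entered the test, so an effect of the cells' CD45 allele alone would largely cancel in the average. In both kinds of host 12 of the 12 genes were lower in donor cells on average. The genes were picked as lower over these same animals, so neither this nor the ILC2-like median is separate evidence against allele or mix. A shorter stay of donor cells in the lung is a hypothesis that was not tested.

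Zbtb16 and Icos were called lower on days 4, 7 and 15 of infection together with T-cell genes, and Il18r1 on days 4 and 7, but not on day 15 (-0.62, limma adjusted p = 0.36). Over the 3 genes and days the median log2 fold change was -1.64 (range -2.97 to -0.62). Fewer T-like cells were argued against as the whole cause for the 3 genes, since without clusters named as other than ILC the median was -1.31 (range -1.82 to 0.43). Icos then stood at -1.44, -1.31 and -0.71 and Zbtb16 at -1.66, -1.82 and -1.53 on the 3 days. For Il18r1 alone the values were -1.08, -0.48 and 0.43 (median -0.48), so fewer T-like cells may be the cause of its change on day 7. It stays open for Il18r1, since the median lay above the bound of -0.5 set for this cause while day 4 lay below the bound of -1 set for any 1 day.

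Of 100 splits of the 8 parabionts' donor and host sums, 1, the real one with 160 genes, gave as many (highest other 25). That argues against chance only if the animals count as separate. They form 4 pairs that exchange cells. Summed by pair, 8 splits are too few for a share under 0.05 (real 37, 1 split with as many, highest other 0). Over all genes the partners' differences did not deviate together (correlation -0.251 to 0.0556). For IL-18, 1 of 33 splits gave as many as the real 82 genes (highest other 7). For DL1, 1 of 33 gave as many as the real 161 (highest other 1). These splits include ones that, unlike the real one, do not balance the other factors. The shares therefore do not exclude chance for IL-18 or DL1. For culture tissue 2 of 33 splits gave as many as the real 12, with 35 as the highest other, so chance is not excluded. For the hosts, where limma called 0 genes (814 with an unadjusted p below 0.05, and 0 with voom), all 35 of 35 splits gave as many, with 30 as the highest other. For the chimeras, 8 splits are too few for a share under 0.05 (real 11, highest other 1).

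The donor and host difference differed by host CD45 allele in 2 genes (497 with an unadjusted p below 0.05; 10 with voom weights); 2 of 35 splits gave as many, with 3 as the highest other, so chance is not excluded for a count of 2. The genes were Ctse (limma adjusted p = 7.45e-05) and Btg2 (limma adjusted p = 0.0231). Ctse was at 129 ± 29.9 CPM in CD45.1 cells against 26.3 ± 11.6 in CD45.2 cells (SD, n = 8 sums from 4 mice per allele), with ranges of 85.2 to 173 and 8.91 to 38.5, and was higher in the CD45.1 cells of all 8 animals, which chance does not explain for this gene. Btg2 stood at 339.7 ± 44 against 487 ± 52.4 and was higher in the CD45.2 cells of all 8 animals. Both lie on chromosome 1 in GENCODE M21, Ctse from 131638306 to 131675505 and Btg2 from 134075170 to 134079120. Ptprc, the CD45 gene, lies on the same chromosome, from 138062861 to 138175708. By experiment the parabiont difference differed in 0 genes with limma (573 with an unadjusted p below 0.05, 1 gene with voom); 35 of 35 splits gave as many, with 3 as the highest other.

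The chimera donor and host difference differed by experiment in 45 genes, 26 higher and 19 lower, with 0 when no low filter was used (1901 with an unadjusted p below 0.05) and 174 with voom weights. Among the 45 were Arg1, Areg, Klrg1, Ccr2, Bcl2 and Ctse. With 2 units per experiment the other splits are too few to judge chance, and the cause of the difference is left open. The donor minus host difference of Zbtb16 in the CD45.2 host of pair 1, experiment 2, was 1.66 log2. It was -1.02 to 0.166 in the other animals, a gap of 0.557 of the whole range. Zbtb16 averaged only 6.19 CPM in donor and 6.32 CPM in host cells. That animal gave 86 donor cells, so its value rests on few transcripts. Of 56 groups of values tested 1 held such a value, and chance alone marks about 1 in 20 groups. Of the wells without a cell name, 33 held at least 1000 transcripts and were not used.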

How the results depend on the processing

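The fits of ILC2-like cells alone, with voom weights or other added values, of day 4 with 2 groups or a mouse block, of chimeras by well-label animal, of parabionts by pair, of marrow gates without a block and of marrow without weights were tests chosen only after results were seen. The cause of the changes below was not tested.

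For marrow against resting lung (2217) counts of genes were 3477 with no low filter, 726 with cells thinned to 1000 transcripts, 3600 without weights, 3397 with a mouse block and 4251 with all gates; leaving out 1 mouse gave 610 to 2597. For day 7 (1211) they were 579 with no filter, 175 thinned, 131 in a fit of only the 2 groups, 407 with a mouse block and 237 to 2243 leaving out 1 mouse. For day 15 (597) they were 301 with no filter, 86 thinned, 1069 with voom and 116 to 265 leaving out 1 mouse. For day 15 against day 7 (1004) they were 497, 219 and, with only the 2 groups, 614, and 99 to 1660 leaving out 1 mouse. For day 4 (661) they were 218 with no filter, 412 without cells of other types, 98 thinned, 1590 with only the 2 groups, 1803 with a mouse block and 45 to 615 leaving out 1 mouse. Deviations of mice with the same number did not go together (correlation 0.0121 for marrow, -0.0381 for day 7 and 0.0325 for day 4), so the numbers pair no samples in these 3 comparisons. For hosts of 1 pair it was -0.245 to 0.174.

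For Lin-Il18r1-Icos+ cells (103) counts were 14 with no filter, 17 thinned and 7 without the mouse block; for Lin-Il18r1+Icos- cells (919) they were 527, 159 and 608. For parabiont donors (160) they were 57 with no filter, 12 in ILC2-like cells, 96 thinned, 241 with voom, 13 without the animal block, 37 summed by pair, 41 in experiment 1, 19 in experiment 2 and 42 to 154 leaving out 1 animal. Between hosts limma called 0 (814 with an unadjusted p below 0.05), as with voom (0, and 883) and with the pair as block (0, and 935); leaving out 1 animal gave 0 to 0. For chimeras (11) they were 0 with no filter (1276 unadjusted), 1 in ILC2-like cells, 0 thinned (365 unadjusted), 6 with an added value of 0.5, 188 with voom, 1 without the unit block, 116 in experiment 1, 495 in experiment 2, 5 by animal of the well labels and 1 to 75 leaving out 1 unit.

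For IL-18 (82) counts were 175 with no filter, 161 with voom and 0 to 110 leaving out 1 arm. For DL1 (161) they were 400 with no filter, 51 thinned, 250 with voom and 42 to 160. For culture tissue (12) they were 289 with no filter, 20 with cells of at least 2000 transcripts, 30 thinned, 20 with an added value of 0.5, 8 with 5, 97 with voom and 0 to 78. Of 227 list tests 95 passed, 2 with an estimated correlation and 32 with fry.

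Directions turned in 13 of 7749 values of named genes. Without cells of other types Ccl5 turned higher in marrow (0.38) and on day 7 (0.80), day 15 (0.33) and day 4 (0.30), and in ILC2-like cells on day 15 (0.22). With all marrow gates Gata3 (-0.43) and Icos (-0.88) turned lower. Cd3e in Lin-Il18r1+Icos- cells became 0.0355 without other types. In parabionts Cd93 became -0.0655 without other types, -1.08 in ILC2-like cells and -0.0342 thinned, and Gm42519 became -0.0665 in ILC2-like cells. Klrg1 in chimeras became -0.34 in experiment 2. Of the rest, 6356 were the same, 1183 weaker, 77 stronger and 120 moved.

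Shares of cell classes depended on clustering, which changed which clusters carried a name. The donor minus host share of ILC2-like cells in chimeras (6.2 points) became -0.822 at resolution 0.5 and -2.07 with cells of at least 2000 transcripts. In parabionts the progenitor-like share (9.05) became -0.294 and -0.151. The ILC2-like share (-21.9) became -4.24 (exact adjusted p = 0.0352) and -7.85 (0.0417). The T-cell-like share (5.39) became 0.738 (0.0352), 5.04 (0.0417) and, at resolution 1.5, 5.44 (0.0391). Another scaling moved the median of all genes by at most -0.0405, on day 7.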

Other observations

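The genes here were picked only after the results were seen, from planned tests.

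Some single homing and receptor genes differed between the marrow gates. In Lin-Il18r1+Icos- cells Il18rap, the second chain of the IL-18 receptor, rose (log2 fold change 1.74, SE 0.17, limma adjusted p = 1.86e-05). Ccr9, a gut and thymus homing receptor gene, fell in those cells (-4.18, SE 0.24, limma adjusted p = 2.43e-07), and so did Stab2, a scavenger receptor gene (-3.96, SE 0.19, limma adjusted p = 5.41e-08). In Lin-Il18r1-Icos+ cells Pdcd1, which encodes PD-1, fell (-1.33, SE 0.25, limma adjusted p = 0.0233). From day 7 to day 15 of infection Ccr9 (-2.52, SE 0.54, limma adjusted p = 0.0178) and Stab2 (-2.09, SE 0.26, limma adjusted p = 0.00164) fell in lung, and Hdc, the histamine-making enzyme gene, rose (4.77, SE 0.89, limma adjusted p = 0.00968).

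In parabionts, donor cells carried more Ms4a4b, a gene of naive lymphocytes (log2 fold change 0.95, SE 0.15, limma adjusted p = 0.00693), and more Cxcr4, a marrow homing receptor gene (0.38, SE 0.08, limma adjusted p = 0.03). Cxcl2, a neutrophil chemokine gene, fell in donor cells (-1.24, SE 0.17, limma adjusted p = 0.00279).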
